A study of Mus musculus with 6 samples.

How the data were processed

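Total RNA from magnetically purified bone marrow monocytes and macrophages of 6 mice was converted to biotinylated cRNA and hybridised to an Illumina mouse whole-genome bead array read in 1 colour, per the labels' protocols. There was 1 array per mouse, with 3 control mice and 3 mice injected with MEC1 cells, grouped by the sample labels. All 6 arrays lay on 1 chip, with the control mice at the first 3 positions and the MEC1 mice at the last 3. Letters name the mice and are not shared between the groups, so samples were not paired.

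The authors deposited a non-normalized table with, per the file headers, a mean signal intensity and a detection p-value for each of 45281 probes on each array. The submitters' processing notes name GenomeStudio, with the version not given in the sources used here. The deposited intensities were on a linear scale with no value below 0. The deposited detection p-value compares a probe with the negative controls of its array. A second deposited table, the series matrix, holds the authors' processed intensity values for the same arrays on a linear scale. Its columns had medians of 100.7 to 100.8, kept each array's order of probes (Spearman's rho of 1) and differed from the mean of the sorted raw signals by at most 1.69, which is what quantile normalization without background subtraction gives. That step was read from the values, since no label states it, and the direction and scale are those of the raw table. This table was used only as an alternative.

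Intensities were background-corrected and normalized with neqc in limma 3.58.1 under R 4.3.3. It fits a normal-exponential model with the mean and spread of negative controls inferred from the detection p-values, adds an offset of 16, applies quantile normalization and takes log2. The offset shrinks the fold changes of dim probes. Probes with a detection p-value under 0.05 on at least 3 of the 6 arrays were tested, which left 16460. Linear models with a group term were fitted by lmFit and moderated by eBayes with an intensity trend and robust variance. Two-sided p-values were adjusted by the Benjamini-Hochberg method over all tested probes, and an adjusted p under 0.05 is a call. SE is the moderated standard error of the log2 change, MEC1 minus control. For a gene not detected on any array of 1 group, a lower bound of the fold is given. It is the bright group's mean against the dim group's mean, with each dim array's value raised to the lowest normalized value among that array's detected probes where it was below it.

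Probes were named from the platform annotation table and symbols were updated through the Entrez ID against the RefSeq gene table. Of the 45281 probes, 34885 had 1 symbol (34807 updated, 78 kept as given), 18 had several and were not named, and 10378 were unnamed here. Where several tested probes named 1 gene, as for 3445 of the 9089 tested genes, the probe with the highest mean normalized value represented it. Probes of 1 gene can disagree, and probes of near-identical genes cannot be told apart by their names. No genome was used, so probe positions and matches to human transcripts were not analysed here.

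Gene lists were fixed from textbook knowledge before the data were examined, 39 in all, on macrophage activation, interferon and antigen presentation, inflammation, metabolism, stress and markers of other marrow cells. Of 867 distinct genes in them, 63 matched no named probe and were not used here. Lists were tested on 1 probe per gene by camera with a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 39 lists. Camera with an estimated correlation and fry, which tests whether the genes of a set move on balance one way, were run as alternatives. Lists share some genes. Genes named in the text are the 12 largest rises and 12 largest falls among called genes whose groups do not overlap, the up to 4 members of each list with the smallest p, and genes of monocyte and macrophage purity. Of the purity genes, 1 matched no named probe and was not used here. Genes outside the rule are said to be chosen after their values were seen.

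The steps were tested on simulated arrays built for the comparison of MEC1 with control mice. These had the background and brightness of the real arrays and, for each probe, a capped spread pooled over both groups. There were 200 changed probes and 5 simulations of about 16500 tested probes each. The share of changed probes called with the right sign was 73.2% for a log2 rise of 2, 47.1% for a fall of 2, 20.8% for a rise of 1 and 21.7% for a fall of 1. Of the 420 probes called, 3.81% had been simulated unchanged. The simulated median estimates were 1.92, -1.79, 0.921 and -0.926. For the gene lists, 2.2% of 500 unchanged random lists had a camera p under 0.05, and 5 of 5 raised lists were found in the right direction. The simulated probes varied independently, unlike real genes, and with the same spread in both groups. The real MEC1 arrays differed more from each other (Pearson's r of 0.923 to 0.967) than the control arrays (0.983 to 0.991). The simulated error share may therefore not hold for the real comparison.

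Alternatives fixed before the data were examined were no background correction, median scaling, the authors' normalized values, an offset of 50, no filter and a stricter filter on dim probes, eBayes without trend and robust variance, array weights, chip position as a covariate, the mean over a gene's probes and leaving out each mouse. A filter on detection on all 6 arrays and the erythroid signal as a covariate were added after seeing the data. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.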

Results

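Gene expression was measured in monocytes and macrophages isolated with magnetic beads from the bone marrow of BALB/c Rag2-/-γc-/- mice, animals without T, B and NK cells that accept human grafts. MEC1, an established human B cell line derived from chronic lymphocytic leukaemia, had been given intravenously to 3 of the mice, and the 3 control mice of the same age received no treatment. All 6 mice were 11 weeks old, and the material was taken on day 21, early in the leukaemia. The comparison asks how the expression of marrow monocytes and macrophages differs when leukaemic B cells are present in the animal. RNA from each mouse was hybridised to 1 single-colour bead array of 45281 mouse probes. The control mice are named A, B and C and the MEC1-injected mice D, E and F. Between 15545 and 16976 probes were detected on an array, or 34.3% to 37.5% of all probes. Median raw intensity was 131, 114 and 115 in control mice A, B and C, and 86.3, 70.7 and 87.6 in MEC1 mice D, E and F. The log2 intensities correlated at Pearson's r of 0.983 to 0.991 across probes between control mice, 0.923 to 0.967 between MEC1 mice and 0.926 to 0.971 across the groups. The number of arrays, 3 per group, limits the precision.

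Of the genes chosen for monocyte and macrophage purity, Ly6c1, Cd14 and Csf1r were bright in both groups, while Itgam and Ptprc were dimmer. Ly6c1, which encodes a Ly6C surface antigen, lay at a log2 intensity of 14.26 ± 0.03 (SD, n = 3) in control mice and 14.20 ± 0.01 (SD, n = 3) in MEC1 mice. Cd14, the lipopolysaccharide co-receptor, lay at 12.24 ± 0.11 and 11.97 ± 0.40, and Csf1r, the receptor for macrophage colony-stimulating factor, at 10.60 ± 0.05 and 10.85 ± 0.39. The macrophage surface marker gene Adgre1 gave 10.02 ± 0.32 and 9.34 ± 0.33, and Itgam, which encodes CD11b, gave 8.38 ± 0.14 and 7.92 ± 0.42. None of these 5 genes passed the test between groups, and neither did Ptprc, which encodes CD45, at 7.66 ± 0.17 and 6.25 ± 1.15. Ptprc was detected on 2 of 3 MEC1 arrays. Other tested probes gave log2 changes of -1.39 to -0.38 for Adgre1, -0.32 for Csf1r and 0.32 for Ptprc. The preparations also held strong signal of other marrow cells in both groups. In control mice the erythroid globin gene Hba-a1 was the brightest probe on each array, at the top of the normalized scale (15.47), with the neutrophil gene S100a8 at 14.88 and the eosinophil granule gene Prg2, singled out after its values were seen, at 15.18.

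The largest rise in mice carrying MEC1 cells was that of Saa3, an acute-phase serum amyloid A protein that macrophages produce. Its log2 intensity went from 5.49 ± 0.27 (SD, n = 3) in control mice, where 1 of 3 arrays detected it, to 12.07 ± 0.61 (SD, n = 3), a log2 change of 6.58 ± 0.31 (SE; adjusted p = 8.7e-05). The other 11 of the 12 largest rises were Ckmt1, Pfn2, Ip6k2, 1700071K01Rik, Upp1, Cxxc4, Carmil2, Efna5, Ppp1r16b, Rbm4 and Nr6a1. Ckmt1, a mitochondrial creatine kinase, was at least 12.2-fold higher (adjusted p = 0.0386), and Pfn2, a profilin that binds actin, at least 11.7-fold higher (adjusted p = 0.0124). Ip6k2, an inositol hexakisphosphate kinase, was at least 13.7-fold higher (adjusted p = 0.0306). Upp1, uridine phosphorylase, was at least 8.91-fold higher (adjusted p = 0.0105), and Efna5, a membrane-bound ligand of Eph receptors, at least 4.25-fold higher (adjusted p = 0.0315). Cxxc4, Carmil2, Ppp1r16b and Nr6a1 were at least 6.77-fold, 5.14-fold, 6.20-fold and 4.29-fold higher. The probes representing these 9 genes were detected on all 3 MEC1 arrays and on no control array, so their folds are lower bounds. Rbm4, an RNA-binding splicing regulator, and the uncharacterised 1700071K01Rik were detected on every array and rose by log2 2.63 ± 0.45 and 3.96 ± 0.55 (SE; adjusted p = 0.0465 and 0.0249).

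The rises of Ckmt1 and Pfn2 belonged to 1 of 2 tested probes. The other tested probe of Ckmt1 gave a log2 change of 0.26 and was detected on 3 control arrays, that of Pfn2 gave 0.45 and was detected on 2, and neither passed the test. All 3 tested probes of Upp1 rose and were detected on no control array, with lower bounds of 8.91-fold, 4.0-fold and 5.01-fold. The second probe of Efna5, also detected on no control array, gave a bound of at least 3.08-fold higher and did not pass (adjusted p = 0.0562). Saa3, Ip6k2, 1700071K01Rik, Cxxc4, Carmil2, Ppp1r16b, Rbm4 and Nr6a1 had 1 tested probe each, so their rises could not be compared between probes. The beta-actin gene Actb and the serine hydroxymethyltransferase gene Shmt2 were singled out after their values were seen. Tested probes of Actb gave log2 changes of -0.65, 0.07, 1.01, 4.36 and 4.51, and none of the 5 passed the test. Those of Shmt2 gave 2.46 (adjusted p = 0.0257) and -0.45 (adjusted p = 0.744). Among the MEC1 mice, mouse E had the highest value in all 12 genes with the largest rise, and mouse D the lowest in 9 of them.

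**Figure D1:**
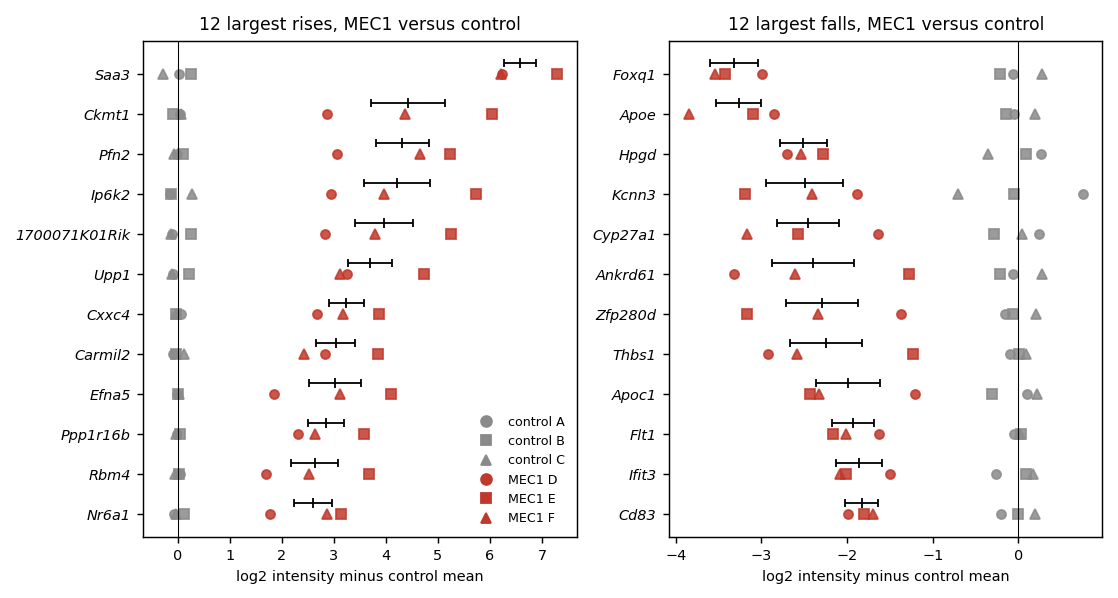
Log2 intensity of each mouse minus the mean of the control mice (x axis) for the 12 genes with the largest rise (left) and the 12 with the largest fall (right). Grey symbols are control mice, red symbols MEC1 mice, and the black bar above each row is the fitted log2 change ± SE; the 3 MEC1 mice lie outside the range of the 3 control mice for each gene, with Saa3 at 6.58 and Apoe at -3.27, and where a group was not detected on any array its plotted change is the measured difference and the text gives a lower bound.

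The largest falls included genes of lipid and sterol handling. Apoe, the apolipoprotein that macrophages secrete with cholesterol, went from 11.38 ± 0.18 (SD, n = 3) to 8.11 ± 0.52 (SD, n = 3), a log2 change of -3.27 ± 0.26 (SE; adjusted p = 0.00219), which is 9.62-fold lower. Apoc1, its neighbour in the same gene cluster, changed by -1.99 ± 0.37 (SE; adjusted p = 0.0393), and Cyp27a1, the mitochondrial sterol 27-hydroxylase, by -2.46 ± 0.36 (SE; adjusted p = 0.0249). The other 2 tested probes of Cyp27a1 fell by 2.69 and 2.29 on the log2 scale. The forkhead transcription factor gene Foxq1 was at least 6.38-fold lower (adjusted p = 0.00255), and Hpgd, which inactivates prostaglandins, at least 3.40-fold lower (adjusted p = 0.00993). Flt1, a receptor for vascular endothelial growth factor, was at least 2.21-fold lower (adjusted p = 0.0129). These 3 genes were detected on all 3 control arrays and on no MEC1 array. Thbs1, the matrix protein thrombospondin, changed by log2 -2.25 ± 0.42, the activation marker Cd83 by -1.83 ± 0.19 and the interferon-induced Ifit3 by -1.86 ± 0.27 (SE; adjusted p = 0.0399, 0.00783 and 0.0192). Kcnn3, a calcium-activated potassium channel, Ankrd61 and Zfp280d completed the 12 largest falls, with log2 changes of -2.50, -2.40 and -2.30. Kcnn3, Ankrd61, Thbs1 and Apoc1 were detected on 1 of 3 MEC1 arrays and Zfp280d on 2 of 3. Their changes are thus measured partly against undetected signal and are less certain.

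Over all 16460 tested probes, limma called 253 at an adjusted p under 0.05, of which 143 were higher and 110 lower in MEC1 mice. Reduced to 1 probe per gene, 158 of 9089 tested genes were called, 86 higher and 72 lower, and 71 of the higher and 56 of the lower ones changed by at least 2-fold. In 34 further genes only a probe other than the one that stood for the gene was called, and the counts of genes and lists leave these out. Of these, Zbp1, Psmb8, Lyz1, Itga4, Dusp2, Cd177 and Ifitm1 are named below and were singled out after their values were seen, while Mif was named by the rule for its list probe. The groups did not overlap in any of the 158 called genes, and they did not overlap in 2633 tested genes, or 29.0%, where chance gives 10% on average for 3 against 3. The genes share the same mice and are not independent, so the share for 1 grouping can lie far from 10%. That share was not computed for other groupings of the mice. The count of called probes was 5 without control mouse A, 9 without B and 9 without C, 1210 without MEC1 mouse D, 67 without E and 135 without F. It was 0 with position on the shared chip as a covariate, a position that differs between the groups (2397 at an unadjusted p under 0.05 in limma). Scaling to a common median in place of quantile normalization moved the median of all tested probes to -0.48 and called 130 higher and 1981 lower, with the direction of all 253 calls kept.

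**Figure D2:**
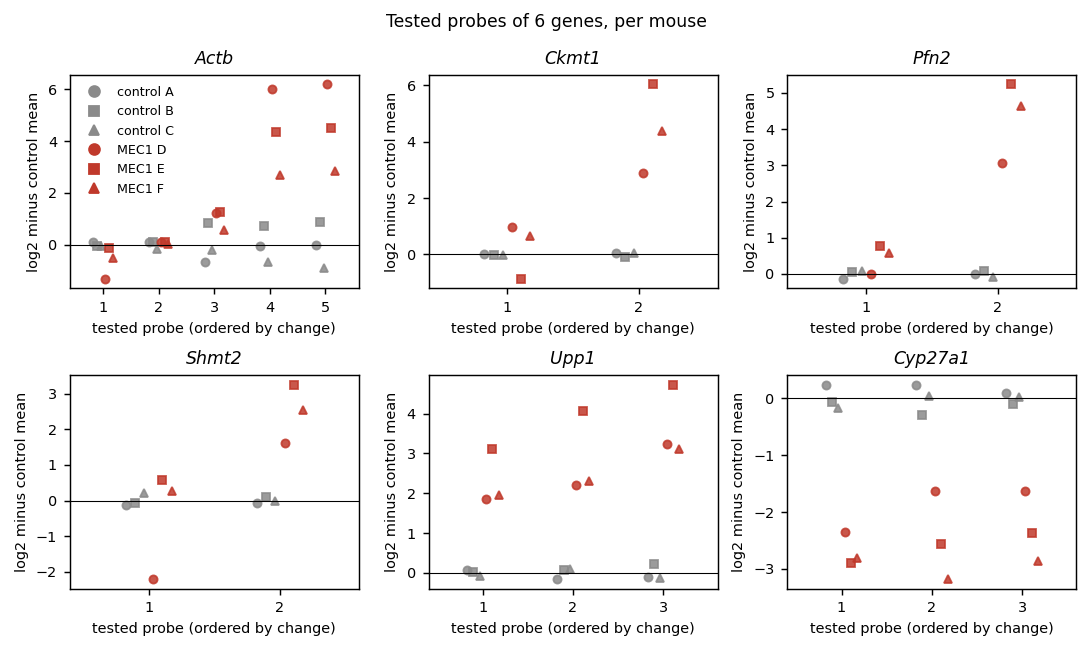
Log2 intensity of each mouse minus the mean of the control mice (y axis) for every tested probe (x axis, ordered by change) of Actb, Ckmt1, Pfn2, Shmt2, Upp1 and Cyp27a1. Grey symbols are control mice and red symbols MEC1 mice; probes of Actb range from a change of -0.65 to 4.51, the 3 of Cyp27a1 from -2.69 to -2.29, and the 3 of Upp1, detected on no control array, are at least 4.0-fold to 8.91-fold higher.

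Among inflammatory genes, changes went both ways. In the list of inflammatory cytokines and NF-kappaB targets, 3 of 24 tested genes rose, 1 fell and 20 did not pass. Beside Saa3, the adhesion molecule gene Icam1 rose by log2 1.16 ± 0.21 (adjusted p = 0.0382) and Tnf by 0.80 ± 0.15 (adjusted p = 0.0426), and Cd83 fell. Adjusted over the list alone, 7 rose and 4 fell. As a set the list did not pass (camera adjusted p = 0.331, and 0.673 with an estimated correlation). In the Toll-like receptor pathway, 1 of 22 genes rose and 1 fell. Lbp, which hands lipopolysaccharide to its receptor, changed by 1.72 ± 0.23 and the RNA sensor Tlr7 by -1.23 ± 0.25 (adjusted p = 0.015 and 0.0496). Adjusted over the list alone, 2 rose and 2 fell, and the set did not pass (adjusted p = 0.812). Socs3, an inhibitor of cytokine signalling, rose by log2 1.37 ± 0.15 (adjusted p = 0.0105) as the only gene of 26 called by its list probe among immediate early genes, a list that also holds genes induced by tissue handling. Another probe of Dusp2 was called there, at 0.84 ± 0.16, while its list probe did not pass (0.51). In that list, adjusted over the list alone, 4 rose and 7 fell, and the set did not pass (adjusted p = 0.206). Lgals3bp, which encodes galectin-3-binding protein, rose by log2 1.03 ± 0.17 in the type I interferon list, in which Ifit3 fell and the other 23 of 25 genes did not pass at their list probes. Another probe of Zbp1, detected on no control array, was called at least 1.84-fold higher, against log2 0.62 at its list probe (adjusted p = 0.271). Adjusted over the list alone, 3 of those genes rose and 2 fell, and the set did not pass (adjusted p = 0.542).

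Acute-phase and iron-binding genes of the heme and iron list were split. Cp, the copper-binding ferroxidase ceruloplasmin, was at least 3.33-fold higher (adjusted p = 0.0129), and Hp, haptoglobin, rose by log2 0.43 ± 0.09 (adjusted p = 0.0488) at 1 of 3 tested probes, with the others at 0.08 and 0.11. Trf, transferrin, changed by log2 -1.46 ± 0.17 (adjusted p = 0.0105). The other 17 of the 20 tested genes did not pass, 3 rose and 2 fell adjusted over the list alone, and the set did not pass (adjusted p = 0.189). Change in both directions was also seen in the matrix list, where the collagenase gene Mmp13 rose by log2 1.58 ± 0.31 (adjusted p = 0.0465), Thbs1 fell and 16 of 18 genes did not pass (set adjusted p = 0.584).

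Genes of alternatively activated and tumour-associated macrophages were called lower as a set by camera with its preset correlation. Of 15 tested genes 3 fell, none rose and 12 did not pass, and 5 fell when adjusted over the list alone (median log2 change -0.29; camera adjusted p = 0.046). With an estimated correlation the list did not pass (adjusted p = 0.533). Clec7a, which encodes the beta-glucan receptor Dectin-1, changed by log2 -1.74 ± 0.15 (adjusted p = 0.0028), the mannose receptor gene Mrc1 by -1.71 ± 0.25 (adjusted p = 0.0207) and the growth factor gene Vegfa by -1.59 ± 0.17 (adjusted p = 0.00783). Fn1, fibronectin, gave -1.36 ± 0.35 and did not pass (adjusted p = 0.122). Under median scaling the median was -0.65, 0.17 below the shift of all tested probes, against 0.27 below it in the main fit. The adjusted p of the set was 0.0591 without control mouse C, 0.118 without MEC1 mouse D and 0.135 without MEC1 mouse F, and 0.114 with chip position as a covariate.

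Markers of monocyte and macrophage subsets did not move in 1 direction as sets. Among 11 tested bone marrow macrophage markers, the high-affinity Fc receptor gene Fcgr1 rose by log2 1.77 ± 0.25 (adjusted p = 0.017), while Mrc1 and the lysozyme gene Lyz2 fell, Lyz2 by 0.45 on the log2 scale (adjusted p = 0.0491). The other 2 tested probes of Lyz2 gave -0.26 and 0.08. The 3 probes of Lyz1 disagreed, with a called fall of 1.47 at 1 probe (adjusted p = 0.0323), a fall that did not pass at a probe detected on no MEC1 array (adjusted p = 0.0562), and -0.04 at the brighter list probe. The median log2 change of that list was -0.04 (camera adjusted p = 0.651), and -0.33 under median scaling, 0.16 above the shift of all tested probes. Of 14 markers of classical monocytes only Hp rose, at 1 of its 3 probes, and none fell, and of 13 markers of nonclassical monocytes only Gngt2, a G protein subunit, rose, by log2 1.84 ± 0.29 (adjusted p = 0.0257). Both sets had a camera adjusted p above the threshold (0.749 and 0.571). Adjusted over the list alone, 1 macrophage marker rose and 3 fell, and 2 classical markers rose and 4 fell. Of the nonclassical markers 2 rose and none fell. Among 17 phagocytic receptors Fcgr1 rose, Clec7a fell and 15 did not pass (set adjusted p = 0.576). In the chemokine list Ccl6 and Ccl9, which attract myeloid cells, changed by log2 -1.48 ± 0.19 and -1.12 ± 0.15 (adjusted p = 0.0139 and 0.015), and the other 11 of 13 genes did not pass (set adjusted p = 0.206). The 5 tested chemokine receptor genes had log2 changes below 0 in each case, with Ccrl2 at -0.95 ± 0.22 and Cx3cr1 at -0.83 ± 0.28, and neither the genes nor the set passed (set adjusted p = 0.0842).

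Glycolysis and hypoxia genes were called higher as a set by camera with its preset correlation. Of 24 tested genes 3 rose, 1 fell and 20 did not pass, 17 had a log2 change above 0, and 10 rose and 1 fell adjusted over the list alone (median log2 change 0.32; camera adjusted p = 0.0459). With an estimated correlation the list did not pass (adjusted p = 0.533). The rises were those of the lactate dehydrogenase gene Ldha, at log2 0.68 ± 0.11 (adjusted p = 0.0249), the phosphoglycerate kinase gene Pgk1, at 0.83 ± 0.13 (adjusted p = 0.0257), and Eno1b, at 1.27 ± 0.25 (adjusted p = 0.0486). Eno1b is nearly identical to the enolase gene Eno1, so its value is uncertain. The gene that fell was Vegfa. Under median scaling the list's median was -0.21, which lies 0.27 above the shift of all tested probes. The median of the list was 0.57 in MEC1 mouse E, which had the lowest erythroid median of the 6 mice (-1.78), and 0.21 and 0.32 in mice D and F. The set's adjusted p was 0.0587 without control mouse A, 0.0942 without MEC1 mouse E and 0.0865 without MEC1 mouse F. It was 0.111 with the erythroid score as a covariate, 0.615 with chip position as a covariate, 0.056 with the mean over a gene's probes and 0.0502 with fry. No gene was called among 34 of oxidative phosphorylation (set adjusted p = 0.189), 37 of the cell cycle (0.349) and 24 of endoplasmic reticulum stress (0.946).

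Lipid genes were represented by Apoe and Apoc1, the 2 of 13 genes of lipid efflux and fatty acid metabolism that fell. Nr1h3, which encodes the oxysterol receptor LXR alpha, was detected on no control array and gave a bound of at least 1.86-fold higher that did not pass (adjusted p = 0.054). Adjusted over the list alone, 1 gene rose and 2 fell, and the set did not pass (adjusted p = 0.113). None of 16 sterol synthesis genes passed, with a median log2 change of 0.22 and 14 of 16 above 0 (set adjusted p = 0.0508). Under median scaling 6 of the 16 lay above 0 and 14 above the shift of all tested probes. Fdps, farnesyl diphosphate synthase, had the smallest p among them, at 0.61 ± 0.14 (adjusted p = 0.075), and was the only one that rose when adjusted over the list alone.

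Genes through which macrophages can act on leukaemic B cells or be recognised by lymphocytes showed few calls. None of 11 support factors for leukaemic B cells passed at its list probe, with Mif at log2 0.45 ± 0.11 and Hgf at -1.06 ± 0.29 (set adjusted p = 0.812), but a dimmer probe of Mif was called, at 1.03 ± 0.15 (adjusted p = 0.0224). Among 15 death ligands and receptors of the TNF family Tnf rose, and Tnfrsf10b, the receptor for TRAIL, gave 1.41 ± 0.29 without passing (adjusted p = 0.0544; set adjusted p = 0.12). Of 20 adhesion molecules only Icam1 was called at its list probe (set adjusted p = 0.942), while another probe of Itga4, detected on no MEC1 array, was called at least 1.25-fold lower. Of 13 MHC class II presentation genes the costimulatory Cd86 fell by 1.10 on the log2 scale (adjusted p = 0.0483; set adjusted p = 0.576). None of 13 MHC class I presentation genes and none of 9 interferon gamma response genes passed at their list probes (set adjusted p = 0.0842 for both), while another probe of Psmb8 was called, at 1.07 ± 0.21, against 0.18 at its list probe. Adjusted over the list alone, 4 MHC class I genes rose and 1 fell, with Psmb9 at 0.83 ± 0.25 and H2-D1 at -0.37 ± 0.09. The other tested probes of H2-D1 gave log2 changes of -0.15 to 0.20.

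Of the lists for other marrow cell types only the erythroid list passed camera with its preset correlation. No single gene of 32 erythroid markers passed, but 31 of them had a log2 change below 0, with a median of -0.88 (camera adjusted p = 3.56e-07). With an estimated correlation the list did not pass (adjusted p = 0.673), nor with fry (0.308). The median of the list relative to the control mean was -0.43, 0.06 and 0.34 in control mice A, B and C and -0.48, -1.78 and -0.41 in MEC1 mice D, E and F, so that mouse E stood apart and mice D and F lay near control mouse A. Car1, carbonic anhydrase, gave -1.45 ± 0.44. Hba-a1 lay at the top of the normalized scale on all 3 control arrays, so its change is not given. In neutrophil lists the stefin gene Stfa1, a member of a family of similar genes, rose by log2 1.91 ± 0.32 (adjusted p = 0.0306) and the granule protease gene Prtn3 by 0.39 ± 0.08 (adjusted p = 0.0483), while a fall of Cd177 was called at a probe other than its list probe (-0.94 ± 0.17), and neither the 22 mature neutrophil genes nor the 13 primary granule genes passed as a set (adjusted p = 0.0857 and 0.0842). No gene was called among 7 eosinophil markers (set adjusted p = 0.15), 11 mast cell and basophil markers (0.576), 7 conventional dendritic cell markers (0.471), 9 osteoclast markers (0.946), 11 stem and progenitor markers (0.749) and 10 stromal and osteoblast markers (0.204). Thbs1 was the 1 gene that fell of 12 megakaryocyte markers, Flt1 of 10 endothelial markers and Tlr7 of 11 plasmacytoid dendritic cell markers, and those sets had adjusted p of 0.812, 0.946 and 0.471. None of 8 B lineage markers passed, with a median log2 change of 0.37 (set adjusted p = 0.0842). None of 7 T and NK cell markers passed, with a median of 0.27 (set adjusted p = 0.15). Under median scaling these 2 medians were -0.11 and -0.16, each above the shift of all tested probes.

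**Figure D3:**
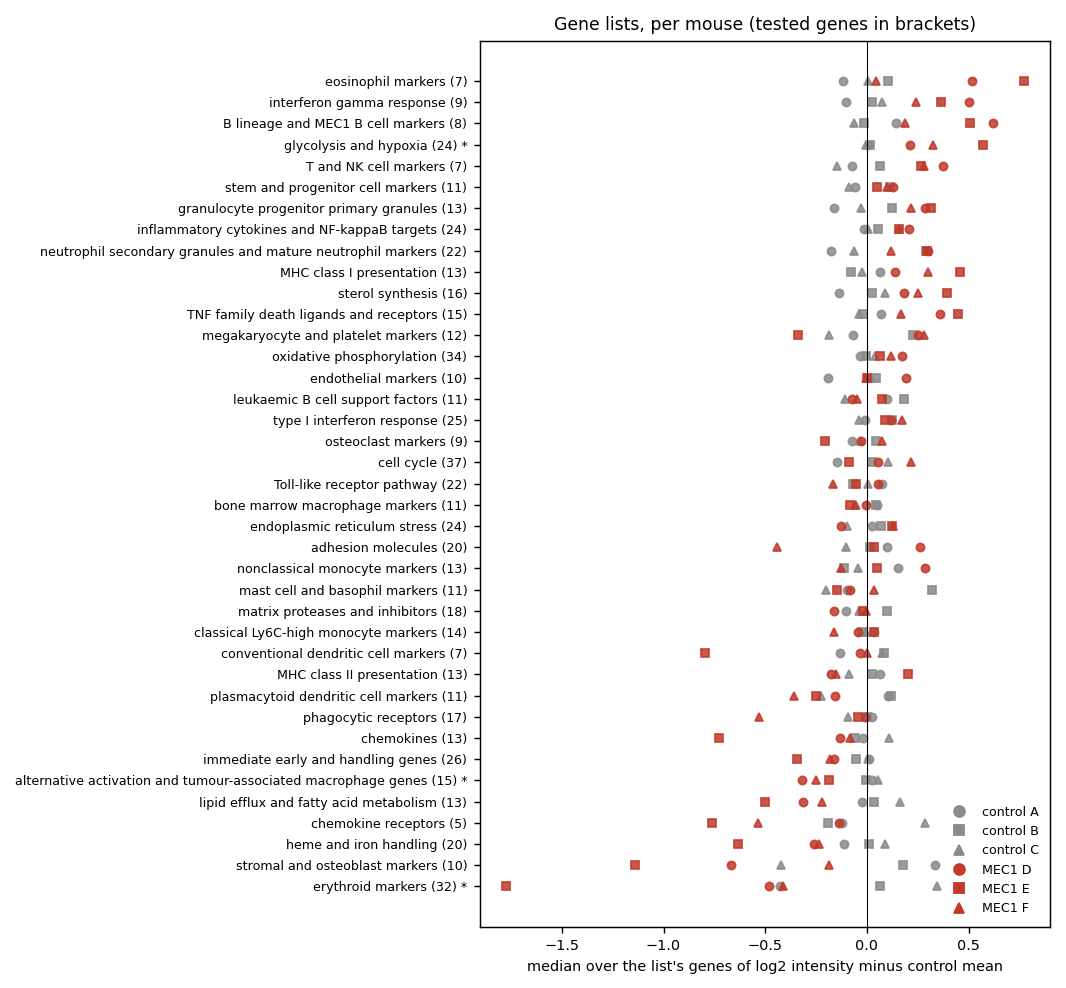
Median over the tested genes of each list of log2 intensity minus the mean of the control mice (x axis), per mouse, for the 39 gene lists (rows, with the number of tested genes in brackets). Grey symbols are control mice, red symbols MEC1 mice, and an asterisk marks the 3 lists with a camera adjusted p under 0.05; the erythroid list lies at -1.78 in MEC1 mouse E.

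Of the 39 lists, camera with its preset correlation called 3, camera with an estimated correlation 0 (1 at an unadjusted p under 0.05) and fry 1, the alternative activation list. The count with the preset correlation was 6 without control mouse B and 1 without MEC1 mouse F, and 1 with chip position as a covariate.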

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

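No paired analysis was possible because the mice share no letters between the groups. The detection filter at 6 arrays and the erythroid covariate were chosen after seeing the data. The 253 called probes kept their sign in each alternative that tested them. The count stayed within 1.5 times (193 to 275) with no background correction, the authors' values, an offset of 50, no filter, the stricter filter and detection on all 6 arrays. It was 2111 with median scaling (130 higher, 1981 lower; 191 of the main calls among them), 95 with eBayes without trend and robust variance (48 higher, 47 lower), 581 with array weights (329 higher, 252 lower), 0 with chip position as a covariate (0 higher, 0 lower; 2397 at an unadjusted p under 0.05 in limma) and 3 with the erythroid score as a covariate (2 higher, 1 lower). Those 3 were Saa3 and probes ILMN_1235435 and ILMN_1239843, named after their values were seen. The position covariate raised the median standard error from 0.256 to 0.513 and the erythroid covariate raised it to 0.311. Leaving out single mice gave 5 to 1210 calls, 2 to 694 higher and 3 to 516 lower. The count was 5 without control A (Saa3, Apoe, Foxq1, Cyp27a1 and ILMN_1235435), 9 without control B or C, 67 without MEC1 E, 135 without MEC1 F and 1210 without MEC1 D. The median standard error was 0.302 to 0.312 without a control mouse, 0.242 without MEC1 D, 0.256 without E and 0.274 without F; the cause of the changed counts was not tested.

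The number of lists called, 3, was 5 with median scaling, 6 with no filter on dim probes, 9 with the stricter filter, 1 with chip position as a covariate, 0 with an estimated correlation (1 at an unadjusted p under 0.05) and 1 with fry, and 1 to 6 without single mice, with 6 without control B and 1 without MEC1 F. The erythroid list kept its call except with the erythroid score as a covariate (adjusted p = 0.306), which removes that signal by construction, an estimated correlation (0.673) and fry (0.308); without single mice it was 3.59e-10 to 5.89e-05, and over the alternatives it ran up to 0.673. The alternative activation list lost its call with chip position (0.114) and an estimated correlation (0.533), and without single mice it ran from 0.00807 to 0.135, past the threshold without control C, MEC1 D and MEC1 F. The glycolysis list lost its call with chip position (0.615), the mean over a gene's probes (0.056), the erythroid covariate (0.111), an estimated correlation (0.533) and fry (0.0502), and without single mice it ran from 0.002 to 0.0942, past the threshold without control A, MEC1 E and MEC1 F. The cause was not tested for the lists' losses with position and without single mice. The camera direction of these 3 lists did not change in any alternative, although the glycolysis list's median fell below 0 (-0.21) under median scaling, where all tested probes shifted to -0.483. Of 48 named genes called, 24 to 48 stayed past the threshold over the alternatives that change only processing and keep all arrays without a covariate (28 of the 28 tested with detection on all 6 arrays), 3 to 5 without a control mouse, 25 to 48 without a MEC1 mouse, 0 with chip position and 1 with the erythroid score, and none turned its direction. Signal over background limits the dim genes. The median net raw signal of tested probes was 123 to 225 on MEC1 arrays and 367 to 405 on control arrays.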

Other observations

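Tests of human RNA, of raw brightness in single risen probes, of erythroid carry-over and of macrophage share were chosen only after the results they concern were seen, as were the genes named in the next 2 paragraphs and, in the last, Slc40a1, Fcna, Hmox1 and Axl.

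Further genes were called higher in MEC1 mice, picked singly and not as members of a tested group. Gpr84, a receptor for medium-chain fatty acids, rose by log2 2.27 ± 0.27 (SE; adjusted p = 0.0119), Bcl3, a co-regulator of NF-kappaB, by 2.10 ± 0.40 (adjusted p = 0.0441), and Lrg1, an acute-phase glycoprotein, by 1.32 ± 0.21 (adjusted p = 0.0259). The complement-related protease gene C1rl rose by 1.83 ± 0.24, the kinase gene Jak3 by 1.59 ± 0.31, and the inhibitory receptor gene Pilra by 1.34 ± 0.21. Cad, which starts pyrimidine synthesis, rose by 2.40 ± 0.31 (adjusted p = 0.014) and Bcat1, a branched-chain aminotransferase, by 2.22 ± 0.27 (adjusted p = 0.0119). Il4i1, a secreted amino acid oxidase, was at least 1.70-fold higher and was detected on no control array. Ifitm1, an interferon-induced membrane protein gene, rose at 2 of its 5 tested probes, by 1.86 and 1.98, while the other 3 gave -0.04, -0.26 and -0.62.

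Called falls, also picked singly, included the leucine zipper gene Tsc22d3, at log2 -1.03 ± 0.16 (adjusted p = 0.0226), and the zinc finger gene Klf9, at -1.29 ± 0.17 (adjusted p = 0.0139). The transcription factor gene Irf4 gave -1.70 ± 0.28 (adjusted p = 0.0269) and was detected on 1 of 3 MEC1 arrays. The surface receptor gene Cd84 was at -1.35 ± 0.19, Cd300lb at -1.76 ± 0.30, Clec4a3 at -1.13 ± 0.16 and P2ry6 at -1.28 ± 0.23. Irs2, an adaptor of insulin signalling, gave -1.25 ± 0.21, the lipid transporter gene Abca9 -1.81 ± 0.31 and the neonatal Fc receptor gene Fcgrt -1.06 ± 0.21. Of the unnamed probes, ILMN_1235435 rose by 6.49 ± 0.34, and ILMN_2541472, detected on no control array, was at least 47.05-fold higher.

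The 6 mice can be split into 3 and 3 in 10 ways, too few for a share under 0.05. By limma the real split called 253 probes and 158 genes, and the highest count of any other split was 0 for both, so that 1 of the 10 splits gave as many. At an unadjusted p under 0.05 the real split gave 3265 probes and the others 119 to 1169. For called lists, 7 of the 10 splits gave at least as many as the real 3, with a highest other count of 11. That split put control mice A and B with MEC1 mouse E, called 0 probes and gave 167 at an unadjusted p under 0.05. The preset correlation of 0.01 is below that estimated for some lists (0.679 for the erythroid list and 0.0339 for the alternative activation list). For the glycolysis list the estimate in the real split was -0.0128, which is not above the preset. Where the preset is too low, a list can pass under any split. Whether the counts of called lists reflect a structure of the samples was not tested. An adjusted p as small as the real one was reached in 4 of the 10 splits for the erythroid list (3.56e-07; smallest other 4.05e-13), in 3 for the alternative activation list (0.046; smallest other 0.0067) and in 3 for the glycolysis list (0.0459; smallest other 0.0192).

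In 15 of 48 called rises of at least 1 log2 unit with another tested probe, no other probe of the gene rose by 0.5, against 6 of 37 such falls (two-sided Fisher's exact p = 0.134). Ckmt1, Pfn2 and Shmt2 were among the 15. In 8 of these 15 probes the raw signal on each MEC1 array exceeded that on each control array. That argues against the dimmer MEC1 arrays and their normalization as the source for those 8. The share over all tested probes, most of them not called, was 0.389%. Probes of other called rises, such as Upp1, Efna5 and Gpr84, also had such raw signals, so this is not particular to the 15. For the other 7 the raw signals overlapped, and brightness as their source stays open. A candidate explanation is RNA of the human MEC1 cells binding to single mouse probes, which would give these probes 1 common order of the MEC1 mice. The order E, F, D was found in 14 of the 15 and in 11 of the 33 other rises (two-sided Fisher's exact p = 0.000116). It was picked after the largest rises were seen, with Ckmt1 and Pfn2 among them. The probes share the same mice and are not independent, so this p only describes the contrast. The order was also found in 4 of the 6 matching falls, which added RNA would not give. From lowest to highest net raw signal the MEC1 arrays were also E, F and D (123, 206 and 225). The order therefore does not tell human RNA from array brightness, and probe-specific change in mouse transcripts was not tested. Magnetic purification is meant to remove MEC1 cells. The B lineage list had a median change of 0.37, with its brightest tested member Cd37 at 9.11 in control and 9.52 in MEC1 mice. Its member Spib, detected on no control array, was at least 1.93-fold higher without passing (adjusted p = 0.167), in the order E, F, D. The other tested Spib probe gave -0.03, and the members Btla, Pou2f2 and Cd37 had other orders. Human RNA and mouse transcripts cannot be told apart here without probe sequences.

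The erythroid list differed among control mice as well as between groups. Without MEC1 mouse E its median change was -0.45 in place of -0.88, and the medians per mouse overlapped between the groups (exact two-sided permutation p = 0.2, where 3 against 3 cannot go below 0.1). Carry-over of erythroid cells that differs between preparations and a lower erythroid output in MEC1 mice cannot be told apart with 3 mice per group; magnetic purification is meant to remove such cells, while Hba-a1 was the brightest probe on each control array. A fit with the erythroid score as a covariate asked whether erythroid signal was the whole source of the other called changes. Over the 253 called probes the share of the log2 change retained had a median of 0.899 and quartiles of 0.798 and 1.03. The median standard error rose from 0.238 to 0.295, and with 1 residual degree of freedom fewer 3 calls were left. Calling favours probes of small spread within a group, while the score varied within groups, and none of the 32 erythroid markers was called. A high retained share was thus partly set by the selection and does not decide this.

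The alternative activation list could be lower because the MEC1 preparations held fewer macrophages. The 11 bone marrow macrophage markers, which share Mrc1 with that list, had a median change of -0.04, which is 0.254 above the list's median of -0.29 and within the spread of the markers (SD 0.917). Their members went both ways, with Mrc1 at -1.71, Slc40a1 at -0.98, Adgre1 at -0.69, Fcna at -0.55 and Lyz2 at -0.45, and Fcgr1 at 1.77, Hmox1 at 0.60 and Axl at 0.34. The other tested probes of Adgre1 gave -1.39 to -0.38. The median of these markers therefore decides nothing and a lower macrophage share stays open. Of 10000 random lists matched on mean level, 1.41% had a median as low. Camera, which also compares a list with the other genes, had already called this list lower on the same values. The share was thus partly set in advance and does not decide on a shift common to genes of that brightness. The random lists do not carry the correlation among the list's genes, and with an estimated correlation the unadjusted camera p was 0.0623. Effects of the dimmer MEC1 arrays on single probes were not tested. The grouping of the mice itself, as given above for the splits, the position on the chip and a change of expression within the macrophages exposed to MEC1 cells also stay open.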
